A study of Rattus norvegicus with 27 samples.

How the data were processed

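Affymetrix arrays hybridised with biotin-labelled cRNA were analysed from the deposited values of 27 samples of rat entorhinal cortex and hippocampus; per the labels the replicates are biological replicates. The deposited values are log2 expression values per probe set, and RMA (robust multi-array average, which corrects background, normalises by quantiles and summarises probes) is named per the submitters' processing notes; the software, its version and any filter of arrays are not given in the sources used here. The unit was read from the values: minima lay between 2.004 and 2.201, medians between 6.001 and 6.088, and maxima between 14.147 and 14.353 in the 27 arrays, so that the arrays of both regions share nearly the same distribution. The values were used as deposited, with no filter on low values. Of 31099 probe sets, 57 Affymetrix controls were left out and 31042 tested.

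Gene symbols came from the array's annotation table and a rat gene table used for names alone, with no coordinates; 20826 probe sets had 1 symbol, 436 had several and 9780 had none listed, for 14217 genes, of which 4525 had more than 1 probe set. Updating symbols through gene identifiers changed 0. Gene values come from the probe set with the highest mean over all 27 arrays, unless a gene was named by a probe set of its own, through its pass or its smallest p. The mean correlation of an array with the other arrays of its group was 0.9892 to 0.9966, the difference between 3′ and 5′ beta-actin probe sets was 2.501 to 3.518, and of 351 pairs of arrays 0 were identical (highest r = 0.9971).

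Each region was fitted alone with limma 3.58.1 in R 4.3.3, with its 4 groups and no other term, and moderated 2-sided p-values were adjusted by Benjamini-Hochberg over all probe sets, with a threshold of 0.05. In each region aged controls were compared with young controls, BDNF with eGFP, eGFP with aged controls and BDNF with aged controls, which makes 8 comparisons; those that use the same aged controls are not independent. In addition 2 interactions, fitted on all 27 arrays, tested whether the age and the BDNF minus eGFP effects differ between the regions. The ageing score of each array is the mean of the 100 probe sets most raised minus that of the 100 most lowered in aged against young controls of the region, and BDNF and eGFP scores were compared by an exact permutation test, 2-sided. Leaving out an array can leave a group with 1 array, which is then assumed to vary like the other groups. Likewise the SE of each comparison within a region draws on the spread of all 4 groups, including groups not compared.

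A set of 28 gene lists (pathways, cell types and tissues that the dissection could hold) was tested by camera from limma with an inter-gene correlation preset at 0.01, with 1 probe set per gene, and by Benjamini-Hochberg over 280 tests. The family was first adjusted as within-region and interaction tests apart and was joined after a first run, with the same numbers of calls. Alternatives were camera with an estimated correlation and fry (with statmod 1.5.0 installed). The lists overlap in part: Vip, for example, belongs to neuropeptides and to GABAergic genes, and Ctss to microglia and to MHC genes. Later 4 lists were written after the data had been seen: cytotoxic lymphocyte genes (17 measured, of which 10 are also in the T and B cell list), erythroid genes (6, all in the blood cell list), MHC class II genes (8, all in the MHC list) and stress-response genes (9).

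Named genes were chosen by a rule. For age and for BDNF against eGFP, the rule takes the 12 rising and 12 falling genes with the largest log2 difference among probe sets with 1 symbol that pass and in which the arrays of the groups do not overlap. Where fewer than 10 pass in a direction it takes all of them, and then up to 5 with the smallest unadjusted p under the same condition, as values that did not pass. Other comparisons take 5 per direction. For each list it takes up to 4 members that passed, or up to 2 with the smallest p (not all are printed, but each that ran against its list is), and a fixed set of genes is given in every comparison: Bdnf, Ntrk2, Arc, Egr1, Vgf, Npy, Sst, Nptx2 (not among the symbols measured), Gfap, Aif1, Cd74, C3, Mbp and Ttr. Interaction genes and genes given for single arrays lie outside the rule and were chosen after their values were seen.

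Groups, comparisons, lists, the named-genes rule and most alternatives were fixed before the data were examined. The alternatives were: the replicate number as a block; only the compared groups in the fit; all 27 arrays in 1 fit; probe sets at or above the median mean; quantile normalization; median centring of arrays; an intensity trend with a robust prior; array weights; 1 probe set per gene; an adjusted p below 0.10; other sizes and sources of the ageing score; other list tests; and leaving out each array in turn. Some were added after seeing the data: list tests under other scalings, a block or left-out arrays, and leaving out together entorhinal eGFP 3 and BDNF 2 of both regions, which stood apart.

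The method was tested on simulated data with the same group sizes, in which 200 of 31042 probe sets were changed, 50 for each size. The changed probe sets were drawn only from those with a mean at or above the median of the region. Recovery of dimmer probe sets was not measured. All sizes were planted in the same simulated data, where the larger changes ease the adjusted threshold for the smaller ones. Noise was normal, with the same spread in every group. The shares that follow can therefore overstate recovery in a comparison with few or no calls. At a log2 change of 1, 92% were recovered for age, 92% for BDNF against eGFP, 94% for eGFP against controls and 96% for BDNF against controls in the entorhinal cortex, and 100%, 84%, 86% and 94% in the hippocampus. At 0.5 the shares were 66%, 60%, 72% and 58% in the entorhinal cortex and 44%, 16%, 40% and 44% in the hippocampus; at 2 and at 4 they were 94% to 100%. False calls numbered 6 to 12, and simulated data with no change gave 0 calls except 1 for eGFP against entorhinal controls. A complement list shifted by 0.3 was called, with 2 of 28 lists called in all. Genes varied independently in these simulated data. The result therefore does not show how the list tests behave when the genes of a list are correlated.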

Results

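Expression was measured on 27 Affymetrix arrays from the brains of young and aged rats, collected 4 weeks after lentiviral infection according to the labels. The vectors carried brain-derived neurotrophic factor (BDNF), a growth factor that signals through the receptor TrkB, or enhanced green fluorescent protein (eGFP), a marker protein that serves as a vector control, and the virus was given in the entorhinal cortex. The entorhinal cortex, which sends the main cortical input to the hippocampus, gave 15 arrays: 4 young control, 4 aged control, 3 aged eGFP and 4 aged BDNF. The hippocampus gave 12 arrays: 4 young control, 4 aged control, 2 aged eGFP and 2 aged BDNF. The labels used here do not state whether the control rats were infused, or whether both regions came from the same rats. Array medians lay between 6.001 and 6.088 on the log2 scale, and the number of arrays limits the precision of each value. All differences are log2 differences ± SE from limma with 2-sided p-values adjusted over 31042 probe sets, and group values are means ± SD.

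Age in the hippocampus was examined by comparing 4 aged with 4 young control arrays. Genes of MHC class II, whose proteins present antigen to helper T cells, rose with age. RT1-Da rose by 2.41 ± 0.27 (8.31 ± 0.40 in aged and 5.89 ± 0.36 in young arrays, n = 4 each, adjusted p = 0.00503), RT1-Bb by 2.34 ± 0.27 (adjusted p = 0.0059; 0.06 at its second probe set). Cd74, the invariant chain that accompanies class II proteins, rose by 2.21 ± 0.24 (8.86 ± 0.34 and 6.65 ± 0.29, adjusted p = 0.00503). RT1-Db1 rose by 1.83 ± 0.26 (adjusted p = 0.018) and by 0.67 at its second probe set. RT1-Ba rose by 1.37 ± 0.19 at 1 of its 4 probe sets (adjusted p = 0.0158), and its brightest probe set differed by 0.03. Fcgr2b, an inhibitory Fc receptor of myeloid and B cells, rose by 1.11 ± 0.09 (7.33 ± 0.06 and 6.22 ± 0.18, adjusted p = 0.000516), and Serping1, which encodes the C1 inhibitor of complement, by 1.25 ± 0.16 (adjusted p = 0.00951). The adhesion gene Cdh1 (E-cadherin) rose by 1.62 ± 0.20 (adjusted p = 0.00839) and stood at 0.09 at its second probe set. Sema3b rose by 1.10, Ecrg4 by 0.98, Cyp2a3 by 0.98 and Ms4a6bl1 by 0.91 (adjusted p from 0.00984 to 0.0445), the last at -0.01 at its second probe set. Ptpro, a receptor-type tyrosine phosphatase gene, fell by 0.76 (SE 0.11, adjusted p = 0.018) and Slc35d3 by 0.75 (SE 0.12, adjusted p = 0.0278). Sema3c (-0.53), Cadm3 (-0.62), Bok (-0.48), Pcdha12 (-0.34) and Tcfl5 (-0.73) did not pass, with adjusted p from 0.0527 to 0.155.

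In all, 32 probe sets changed with age in the hippocampus, 29 higher and 3 lower. They represent 24 genes that rose and 2 that fell, and 5 probe sets had no single gene symbol. At an unadjusted p below 0.05 there were 2362 probe sets where chance gives 1552, and 7 of 35 splits of the 8 arrays, the real one included, gave as many. In 4.92% of probe sets the aged and young arrays did not overlap, where chance gives 2.86%. RT1-Da, RT1-Bb, Cd74, Cdh1 and Fcgr2b passed without each of the 8 arrays in turn. Serping1 did not pass without young control 4 (adjusted p = 0.0514), nor Ms4a6bl1 without young control 3 or 4 (0.0513 and 0.0514). RT1-Ba was lost without young control 2, 3 or 4 or aged control 1 or 4 (0.0513 to 0.0699). Ecrg4 was lost without young control 2 or 3 or aged control 1, 3 or 4 (0.0513 to 0.0699), and Cyp2a3 without young control 2, 3 or 4 or aged control 2 or 3 (0.0606 to 0.132). Ptpro was lost without young control 2, 3 or 4 or aged control 3 or 4 (0.0514 to 0.0866), and Slc35d3 without young control 1, 2 or 3 or aged control 1, 3 or 4 (0.0542 to 0.132). Of the 8 omissions RT1-Db1 passed only without aged control 2 (0.0504 to 0.088 without the others), and Sema3b only without young control 1 (0.0659 to 0.172 without the others). The count was 7 without young control 3, 9 without young control 2, 11 without young control 4, 12 without aged control 3, and 14 without aged control 1 or aged control 4. With all 27 arrays in 1 fit, in which both regions share 1 variance, calls ended for RT1-Da (adjusted p = 0.395), RT1-Bb (0.416), Cd74 (0.406), RT1-Db1 (0.541), RT1-Ba (0.637), Serping1 (0.189), Cyp2a3 (0.102), Ptpro (0.664), Lgals3 (0.481) and Cd53 (0.197). The call of Cd53 also ended with only the control groups in the fit (0.104), that of RT1-Db1 with an intensity trend (0.0604) and that of Sema3b with array weights (0.051).

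Among the gene lists, microglia and macrophage markers were higher in the aged hippocampus (median 0.365, list adjusted p = 4.74e-21, adjusted p = 0.144 with an estimated correlation). Of 29 measured members 3 rose (Fcgr2b, Lgals3 by 0.67 ± 0.11 and Cd53 by 0.63 ± 0.10), 19 rose when adjusted over the list alone, and 26 did not pass over all probe sets. Left-out arrays ended the calls of Lgals3 and Cd53 except in the case of aged control 2 (Lgals3 0.077 to 0.143 and Cd53 0.0575 to 0.164). Both calls also ended with the replicate number as a block. The complement list, genes of an innate immune cascade, was higher by a median of 0.193 (list adjusted p = 8.87e-07, adjusted p = 0.144 with an estimated correlation), with 1 of 17 members rising (Serping1) and 7 when adjusted over the list alone. MHC and antigen presentation genes were higher by a median of 0.133 (list adjusted p = 4.6e-09, adjusted p = 0.549 with an estimated correlation), with 4 of 26 rising (RT1-Da, RT1-Bb, Cd74 and RT1-Db1) and 8 when adjusted over the list alone. Oligodendrocyte and myelin markers were higher by a median of 0.234 (list adjusted p = 1.3e-08, adjusted p = 0.697 with an estimated correlation). Of 31 members 0 passed in limma over all probe sets and 2 when adjusted over the list alone, Cryab (0.53 ± 0.12) and Myrf (0.50 ± 0.11). Astrocyte markers were higher by a median of 0.11 (list adjusted p = 0.000358, adjusted p = 0.697 with an estimated correlation), with 1 of 28 past the threshold when adjusted over the list alone (Vim, 0.58 ± 0.13). Mitochondrial respiratory chain genes had a median of -0.098 (list adjusted p = 2.65e-07, adjusted p = 0.739 with an estimated correlation), with 49 of 52 members below 0, for example Ndufv3 (-0.22 ± 0.10, or -0.13 without young control 4). Blood cell genes were higher by a median of 0.117 (list adjusted p = 0.0186, adjusted p = 0.739 with an estimated correlation). That call was lost without young control 4 or aged control 1 (up to 0.159). Cytosolic ribosomal proteins had a median of -0.055 (list adjusted p = 0.0161, adjusted p = 0.868 with an estimated correlation), a call lost without young control 4 or aged control 3 (up to 0.824). Aged control 3 stood apart in the difference between 3′ and 5′ beta-actin probe sets, a measure of RNA integrity: 3.52, where the other aged hippocampal controls reached 2.84.

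**Figure D1:**
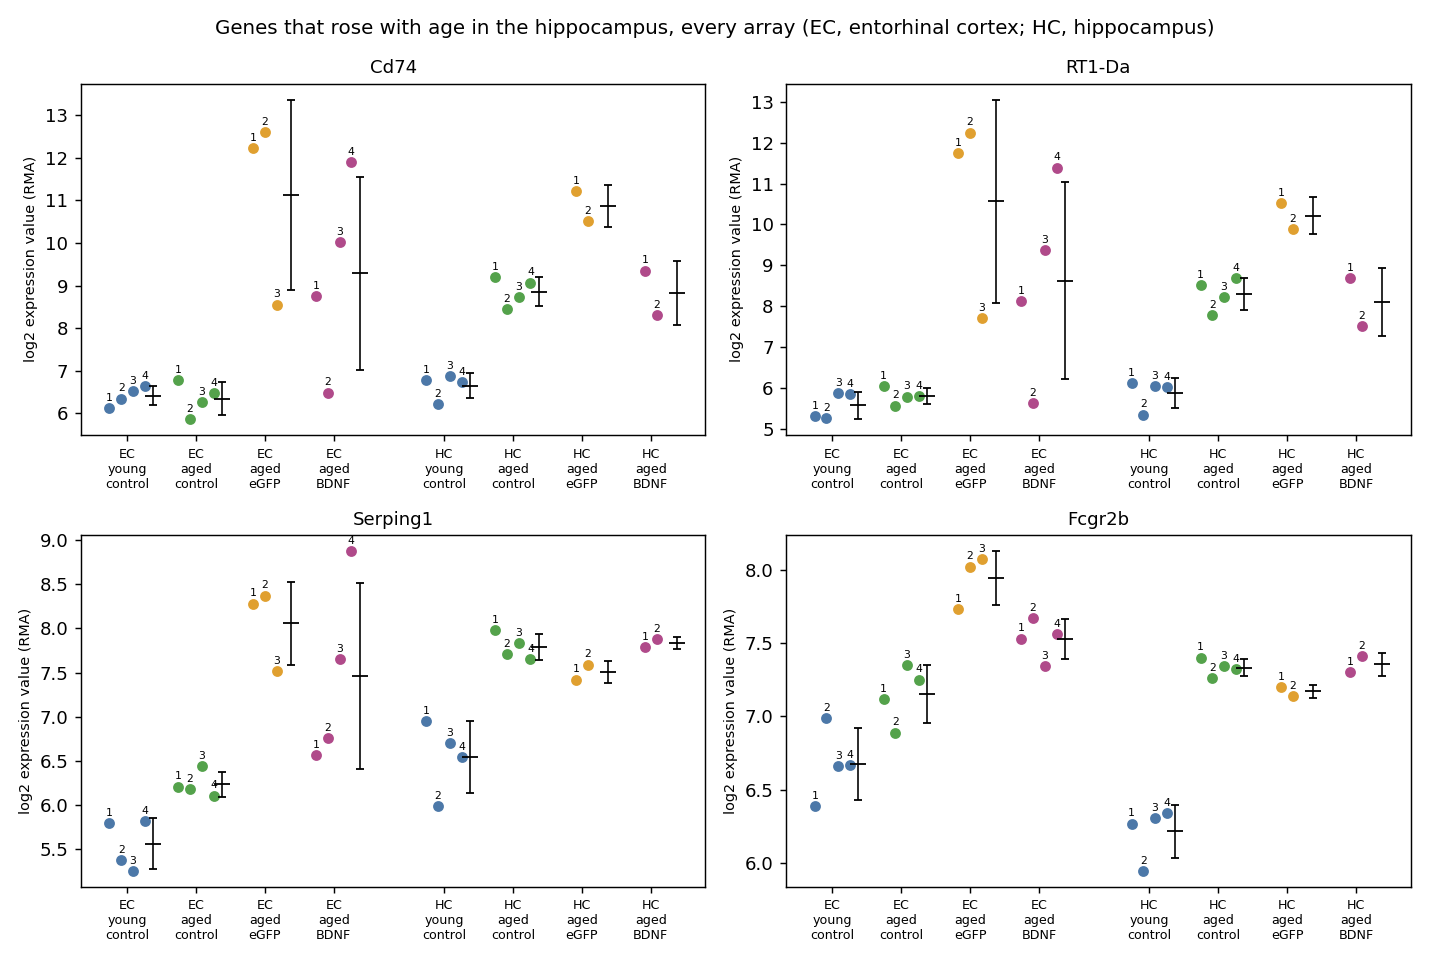
Log2 expression value (RMA, y axis) of Cd74, RT1-Da, Serping1 and Fcgr2b in each array of both regions (x axis: group; points numbered by replicate; bars are mean ± SD). In the hippocampus Cd74 was 8.86 ± 0.34 in aged and 6.65 ± 0.29 in young controls, and 10.86 ± 0.50 in eGFP arrays.

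Age in the entorhinal cortex was examined in the same way, with 4 aged and 4 young control arrays. The genes with the smallest p-values were Cdh1 (1.05 ± 0.18; 4.43 ± 0.39 in aged and 3.37 ± 0.14 in young arrays, n = 4 each, limma adjusted p = 0.796) and Cdh23, a cadherin gene (0.89 ± 0.16; 6.18 ± 0.14 and 5.29 ± 0.08, adjusted p = 0.869). Neither passed, nor did Ecrg4 (0.81), Jhy (0.60), Susd2 (0.39), Rhobtb1 (-0.31), Csrp2 (-0.40), Olfml2a (-0.44), Crb2 (-0.47) or the collagen gene Col3a1 (-0.80 ± 0.16). By limma 0 probe sets changed, with 847 at an unadjusted p below 0.05 (506 higher and 341 lower) where chance gives 1552. With only the control groups in the fit, 1 probe set changed.

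All 5 lists called with age in the entorhinal cortex were lower. Immediate early genes, which neurons switch on with activity, had a median of -0.082 (list adjusted p = 0.00274, adjusted p = 0.739 with an estimated correlation), with 26 of 35 below 0, for example Ptgs2 (-0.66 ± 0.27), but Gadd45b at 0.29 ± 0.12 (0.19 without aged control 2). Endothelial and mural cell markers had a median of -0.074 (list adjusted p = 0.00145, adjusted p = 0.697 with an estimated correlation), with Tek at -0.31 ± 0.12. Meningeal and fibroblast genes had a median of -0.062 (list adjusted p = 0.00274, adjusted p = 0.697 with an estimated correlation), and Col3a1 fell when adjusted over the list alone (limma adjusted p = 0.00467). Neocortical and entorhinal neuron genes had a median of -0.049 (list adjusted p = 0.0085, adjusted p = 0.697 with an estimated correlation; Nectin3 -0.63 ± 0.21, Foxp2 -0.67 ± 0.23), and cytosolic ribosomal proteins of -0.024 (list adjusted p = 0.0357, adjusted p = 0.884 with an estimated correlation). No member of the 5 lists passed over all probe sets in limma. Each call was lost without some array. List adjusted p reached 0.544 for immediate early genes (without young control 1 or 4 or aged control 1) and 0.409 for endothelial genes (young control 2). It was 0.0829 for meningeal genes (aged control 4), and reached 0.309 for neocortical genes (young control 1 or 3, aged control 2) and 0.313 for ribosomal genes (young control 2, aged control 2 or 4), whose direction turned without young control 2.

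BDNF was compared with the eGFP vector control in the aged entorhinal cortex (4 and 3 arrays), where the virus was given. The Bdnf transcript itself differed by 0.10 ± 0.22 (8.23 ± 0.14 in BDNF and 8.13 ± 0.34 in eGFP arrays, n = 4 and 3, limma adjusted p = 0.975). Whether its probe set reads the vector's transcript is unknown. Neuropeptide genes were higher in BDNF arrays (median 0.138, list adjusted p = 0.00114, adjusted p = 0.634 with an estimated correlation). Among them Vip, a peptide of cortical interneurons, stood at 0.63 ± 0.16 (9.96 ± 0.36 and 9.34; limma adjusted p = 0.0329 over the list alone), Npy at 0.45 ± 0.19 and Sst at 0.21. Immediate early genes were higher by a median of 0.159 (list adjusted p = 8.13e-05, adjusted p = 0.739 with an estimated correlation), with 29 of 35 above 0 and 0 passing when adjusted over the list alone. Arc stood at 0.72 ± 0.53 and Egr1 at 0.24, or at 1.23 and 0.51 without BDNF 2 and 0.31 and 0.08 without eGFP 3. Without BDNF 3 they stood at 0.34 and 0.07, and Arc at 1.13 without eGFP 2. Both were low in BDNF 2 (Arc 7.77, Egr1 11.07) and eGFP 3 (7.76 and 11.31), which also had the highest stress-response means of the region (8.72 and 9.28), and the list mean was 7.607 in BDNF 2 and 7.706 in eGFP 3 against 7.829 to 8.32 in the other arrays of both groups. Oligodendrocyte and myelin markers were lower, with a median of -0.234 (list adjusted p = 1.57e-05, adjusted p = 0.739 with an estimated correlation), with 28 of 31 below 0, for example Myrf at -0.43 ± 0.14 and Tspan2 at -0.43 ± 0.15.

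Other neuronal lists were also higher in BDNF than in eGFP entorhinal arrays. Potassium and calcium channels had a median of 0.098 (31 of 41 above 0, list adjusted p = 0.000195, adjusted p = 0.549 with an estimated correlation), with Kcnj3 at 0.45 ± 0.17. GABAergic neuron genes had 0.076 (19 of 24, list adjusted p = 0.000526, adjusted p = 0.549 with an estimated correlation), and Vip passed over that list alone (limma adjusted p = 0.0344). The median was 0.103 for neocortical and entorhinal neuron genes (22 of 29, 0.00113; Rorb 0.53 ± 0.21, or 0.35 without eGFP 3), with feedback genes of the ERK pathway at 0.127 (14 of 16, 0.00467; Etv5 0.67 ± 0.29, or 0.31 without eGFP 3 and 1.06 without eGFP 1, but Il1rap -0.24 ± 0.12, or -0.11 without eGFP 2). Both had adjusted p = 0.549 with an estimated correlation. Pan-neuronal markers had 0.054 (18 of 23, list adjusted p = 0.0135, adjusted p = 0.697 with an estimated correlation), with Nrxn3 at 0.38 ± 0.15 (0.24 without eGFP 3). Immune and glial lists were lower. Microglia and macrophage markers had a median of -0.254 (26 of 29 below 0, list adjusted p = 0.00113, adjusted p = 0.739 with an estimated correlation), with Fcgr1a at -0.60 ± 0.19 (-0.36 without eGFP 2). Complement had -0.187 (15 of 17, 0.00751, C1qc -0.56 ± 0.20) and astrocyte markers -0.105 (25 of 28, 0.0084, Mt1 -0.35 ± 0.14, or -0.23 without eGFP 3), each with adjusted p = 0.739 with an estimated correlation. The others were MHC and antigen presentation (-0.192, 20 of 26, 0.0147; Ctss -0.27 ± 0.11) and interferon response (-0.171, 30 of 37, 0.0161; Irf9 -0.33 ± 0.09). With an estimated correlation they had adjusted p = 0.786 and 0.807. Ribosomal proteins had a median of -0.067 (list adjusted p = 0.00274, adjusted p = 0.795 with an estimated correlation). BDNF 2 had the highest blood list mean of its group (6.17, the others up to 5.43). Blood cell genes (median 0.173, 13 of 16 above 0, list adjusted p = 0.00131; Hbb 1.23 ± 0.41, or 0.78 without BDNF 2 and 0.75 without eGFP 3, but Gng11 -0.28 ± 0.12, or -0.16 without eGFP 3) and T and B cell markers (0.153, 0.008; Cd247 0.40 ± 0.13) were higher in BDNF arrays, with adjusted p = 0.651 and 0.739 with an estimated correlation.

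Between BDNF and eGFP in the entorhinal cortex 0 probe sets changed by limma (smallest adjusted p = 0.908), with 1487 at an unadjusted p below 0.05 where chance gives 1552. The named genes with the smallest p-values were Ptger1 (0.47), Mast2 (0.46), Hand1 (0.45), Rasa2 (0.45) and Nfkbiz (0.41) on the higher side and Fcna (-0.73), Rps24 (-0.63), Cyp2j10 (-0.60), Klkb1 (-0.59) and Gsta1 (-0.38) on the lower side. Without each of the 7 arrays in turn the calls stood for immediate early, neuropeptide, GABAergic, channel, myelin, blood and neocortical genes (list adjusted p at most 0.0445). Calls were lost for ERK feedback genes without eGFP 3 (0.135), pan-neuronal markers without eGFP 2, eGFP 3 or BDNF 2 (up to 0.214) and ribosomal proteins without eGFP 2 (0.433). Those of complement and microglia without eGFP 1, eGFP 2 or BDNF 1 were lost (up to 0.229 and 0.591), and those of MHC and interferon genes without eGFP 1, eGFP 2, BDNF 1 or BDNF 2 (up to 0.901 and 0.993), with interferon genes turning direction without eGFP 2. Astrocyte markers lost theirs without eGFP 2, BDNF 1 or BDNF 3 (up to 0.472) and T and B cell markers without eGFP 3, BDNF 2 or BDNF 4 (up to 0.527).

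In the hippocampus BDNF was compared with eGFP on 2 arrays each. None of the named genes passed by limma. Cd74 stood at -2.04 ± 0.34 (8.82 ± 0.74 and 10.86 ± 0.50, n = 2 each, limma adjusted p = 0.297), RT1-Da at -2.10 ± 0.38 (adjusted p = 0.351) and RT1-Ba at -1.95 at 1 of its 4 probe sets (adjusted p = 0.0544; -0.22 at the brightest). The MHC list had a median of -0.192 (list adjusted p = 2.53e-10, adjusted p = 0.549 with an estimated correlation), with 0 of 26 members passing in limma over all probe sets and 4 lower when adjusted over the list alone. Interferon response genes had a median of -0.225 (list adjusted p = 9.64e-06, adjusted p = 0.697 with an estimated correlation), and the chemokine gene Cxcl9 fell when adjusted over the list alone (-1.14 ± 0.22, limma adjusted p = 0.00588). Microglia and macrophage markers had a median of -0.092 (list adjusted p = 0.0114, adjusted p = 0.739 with an estimated correlation; Fcgr3a -0.69 ± 0.19, or -0.36 without BDNF 2, but Cd14 0.47 ± 0.14). In the blood cell list hemoglobin genes were higher, Hbb by 1.70 ± 0.36 and Hba-a3 by 0.97 ± 0.24 (limma adjusted p = 0.00677 and 0.0103 over the list alone; list median 0.127, list adjusted p = 0.0165, adjusted p = 0.739 with an estimated correlation). Hippocampal BDNF 2 had Hbb at 11.88, where no other hippocampal array passed 10.18. Without it Hbb stood at 0.85 and Hba-a3 at 0.51.

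Lists with small higher medians in hippocampal BDNF than eGFP arrays were mitochondrial genes (0.05, list adjusted p = 0.023, Ndufa5 0.32 ± 0.13, or 0.16 without BDNF 2) and endothelial and mural cell markers (0.025, list adjusted p = 0.0189, Abcb1a 0.54 ± 0.16). With an estimated correlation they had adjusted p = 0.874 and 0.728. Astrocyte markers had 0.072 (list adjusted p = 0.0282, Itih3 0.58 ± 0.16) and myelin markers 0.081 (list adjusted p = 0.0342), with adjusted p = 0.739 and 0.808 with an estimated correlation. In the myelin list Cryab (0.61 ± 0.17) and Mal (0.52 ± 0.15) were higher over the list alone (limma adjusted p = 0.0493 each), with Cryab at 0.33 without BDNF 2. The limma test called 0 probe sets, with 1213 at an unadjusted p below 0.05 (417 higher and 796 lower). The genes named by smallest p were Hbb, Vsig10 (0.84), Cp (0.69), Ptpn11 (0.53) and Hba-a3 on the higher side and RT1-Ba, Cd74, Ubd (-1.41), Plac8 (-1.07) and Cga (-0.77) on the lower side (adjusted p from 0.0544 to 1). Without BDNF 1, which leaves BDNF 2 alone in its group, Cd74 stood at -2.56, C3 at -2.27 and Hbb at 2.55. Each of the other omissions likewise left a group with 1 array. The MHC call stood without each of the 4 arrays (list adjusted p at most 0.00128). Calls of mitochondrial (up to 0.761) and microglia genes (up to 0.114) were lost without eGFP 1 or BDNF 2, and that of interferon genes without BDNF 2 (0.951). Astrocyte (up to 0.212) and myelin genes (up to 0.138) lost theirs without eGFP 2 or BDNF 1, the latter turning the direction of myelin genes. The same held for endothelial genes without eGFP 1 or BDNF 1 (up to 0.502), and blood genes without eGFP 2 or BDNF 2 (up to 0.95), with blood genes turning without BDNF 2.

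The vector control was compared with aged controls in the entorhinal cortex (3 and 4 arrays). No named gene passed by limma in this comparison. Cd74 stood at 4.77 ± 0.99 (11.12 ± 2.23 in eGFP and 6.35 ± 0.39 in control arrays, n = 3 and 4, limma adjusted p = 0.179), with single arrays at 12.22, 12.60 and 8.55. Clec4a3, a C-type lectin receptor gene, stood at 1.23 ± 0.17 (6.97 ± 0.24 and 5.74 ± 0.17, adjusted p = 0.0555), the co-stimulatory gene Cd86 at 0.96, the RNA sensor gene Tlr7 at 0.98, Tagap at 0.83 and Irf9 at 0.57 (adjusted p from 0.0581 to 0.0714). On the lower side Xkr5 (-0.41), Padi3 (-0.49), Slc12a7 (-0.39), Zfp362 (-0.46) and Mast2 (-0.48) had the smallest p-values.

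Microglia and macrophage markers were higher in entorhinal eGFP than aged control arrays by a median of 0.479 (list adjusted p = 8.74e-10, adjusted p = 0.697 with an estimated correlation), and 11 of 29 rose when adjusted over the list alone, among them Fcgr2b (0.79 ± 0.14). Interferon response genes were higher by 0.434 (list adjusted p = 5.23e-08, adjusted p = 0.723 with an estimated correlation). Over the list alone 4 of 37 rose, among them Irf9 and Ifit2 (0.54 ± 0.11). For complement the median was 0.404 (list adjusted p = 8.26e-06, adjusted p = 0.651 with an estimated correlation), and 8 of 17 rose over the list alone, among them C1qc (1.10 ± 0.20) and C1qa (0.91 ± 0.17). For MHC genes it was 0.394 (list adjusted p = 3.7e-07, adjusted p = 0.697 with an estimated correlation), and 10 of 26 rose over the list alone, among them Cd74 and Ctss (0.48 ± 0.11). Ribosomal proteins were higher in 39 of 41 members (median 0.111, list adjusted p = 8.26e-06, adjusted p = 0.739 with an estimated correlation; Rpl24 0.26 ± 0.08). Neuronal lists were lower. Pan-neuronal markers had a median of -0.072 (list adjusted p = 0.00193, Nrxn3 -0.41 ± 0.15, or -0.27 without eGFP 3). The others were potassium and calcium channels (-0.051, 0.00196; Kcnn1 -0.25 ± 0.09), GABAergic genes (-0.109, 0.00904; Calb2 -0.34 ± 0.15) and ERK feedback genes (-0.106, 0.00983; Spry2 -0.22 ± 0.10), with adjusted p = 0.651, 0.549, 0.697 and 0.549 with an estimated correlation. Choroid plexus genes had a median of -0.061 (list adjusted p = 0.00647, adjusted p = 0.697 with an estimated correlation), and Aqp1 fell over the list alone (-0.45 ± 0.12, limma adjusted p = 0.0459). Cholesterol synthesis genes had -0.066 (list adjusted p = 0.023, adjusted p = 0.787 with an estimated correlation), with 18 of 22 below 0, but Ggps1 at 0.32 ± 0.11 and Insig2 at 0.15 ± 0.08.

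**Figure D2:**
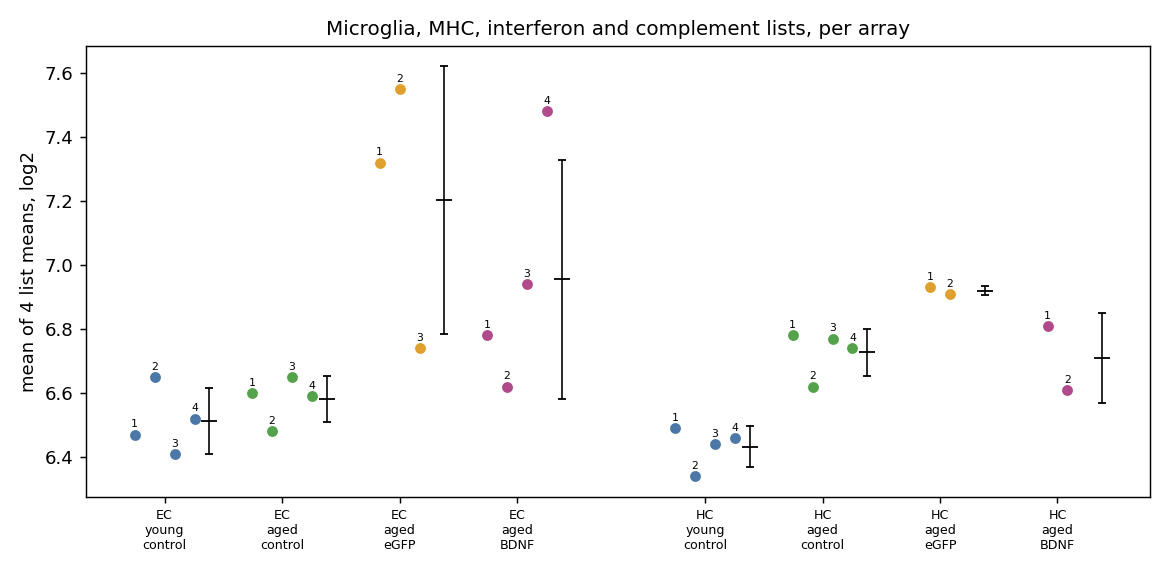
Mean log2 value (y axis) of the microglia, MHC, interferon and complement lists in each array by group and region (x axis; points are arrays, bars are mean ± SD). The entorhinal eGFP arrays stood at 7.32, 7.55 and 6.74, and the aged entorhinal controls between 6.48 and 6.65.

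Between eGFP and aged control entorhinal arrays 0 probe sets changed by limma, with 3006 at an unadjusted p below 0.05 (1624 higher and 1382 lower) where chance gives 1552. The array eGFP 3 had the lowest mean correlation with its group (r = 0.9892), and without it 169 probe sets changed, among them Cd74 (6.06, adjusted p = 0.011), Clec4a3, Cd86, Tlr7 and Irf9. Without aged control 3 there was 1, Tlr7 (1.11, adjusted p = 0.0271). The counts were 70 with array weights, 38 with all 27 arrays in 1 fit, 8 with 1 probe set per gene, 3 each with quantile normalization, the brighter probe sets alone or an intensity trend, and 2 with only both groups. Calls of the 4 immune lists and of ribosomal, pan-neuronal and channel genes stood without each of the 7 arrays (list adjusted p at most 0.0349). Those of ERK feedback (up to 0.135) and cholesterol genes (up to 0.22) were lost without aged control 2 or eGFP 3, with cholesterol genes turning direction without eGFP 3. The same held for GABAergic genes without aged control 1, eGFP 2 or eGFP 3 (up to 0.0659), and choroid plexus genes without eGFP 1 or eGFP 2 (up to 0.107).

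BDNF was also compared with aged controls in the entorhinal cortex (4 arrays each). All 25 measured T and B cell markers were above 0 in BDNF arrays (median 0.413, list adjusted p = 1.16e-09, adjusted p = 0.549 with an estimated correlation), with 0 passing in limma over the list alone. Ccl5, a chemokine of T cells, stood at 1.74 ± 0.52 (1.11 without BDNF 2) and the cytokine receptor gene Il2rg at 0.87 ± 0.25. The list mean was 5.113 in BDNF 2 and 4.883 in BDNF 4, and 4.126 and 4.422 in BDNF 1 and 3. These high arrays differed: the T cell markers Cd3d, Cd3e and Cd3g were 4.30, 5.93 and 5.51 in BDNF 4 but 2.90, 4.59 and 3.15 in BDNF 2, below the medians of the other entorhinal arrays (3.13, 4.85 and 3.43). The B cell marker Ms4a1 was 3.86 in BDNF 2, where that median was 4.05. Microglia and macrophage markers were higher by a median of 0.264 (list adjusted p = 5.11e-07, adjusted p = 0.72 with an estimated correlation), with Lgals3 rising when adjusted over the list alone (1.27 ± 0.31, limma adjusted p = 0.0238). Interferon response genes (0.238, list adjusted p = 1.05e-06; Rsad2 1.08 ± 0.29), MHC genes (0.211, 2.91e-06; RT1-Bb 3.11 ± 0.98) and complement (0.264, 0.000839; Serping1 1.23 ± 0.36, or 0.76 without BDNF 4) had adjusted p = 0.739, 0.723 and 0.697 with an estimated correlation. Cd74 was 9.28 ± 2.26 in BDNF arrays (8.75, 6.49, 10.01 and 11.89). Ribosomal proteins (0.048, list adjusted p = 0.00981), immediate early genes (0.111, 0.0155; Atf3 0.52 ± 0.19) and neocortical neuron genes (0.076, 0.023; Foxp2 0.81 ± 0.23) were higher, with adjusted p = 0.808, 0.787 and 0.697 with an estimated correlation. Myelin markers were lower (-0.127, list adjusted p = 0.00123, adjusted p = 0.739 with an estimated correlation).

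Among single genes the smallest p-value of this comparison was that of Tagap, a T cell activation gene (0.81 ± 0.12; 4.36 ± 0.26 in BDNF and 3.55 ± 0.11 in aged control arrays, n = 4 each, limma adjusted p = 0.149). Slfn4 (0.84), Ch25h (0.69), Clec4a3 (0.68), Slc25a13 (0.41), Unc13c (-0.64), Cav2 (-0.36), Mybl2 (-0.32), Slc12a7 (-0.30) and Arhgef10l (-0.23) did not pass. By limma 0 probe sets changed, with 1117 at an unadjusted p below 0.05 (562 higher and 555 lower) where chance gives 1552. Microglia and T and B cell calls stood without each of the 8 arrays (list adjusted p at most 0.0114). Complement, MHC and interferon genes lost theirs without BDNF 4 (0.0891, 0.0509 and 0.136). Immediate early genes lost theirs without aged control 1 or 3 or BDNF 1 or 3 (up to 0.836) and myelin markers without aged control 2 or BDNF 1 or 2 (up to 0.309), with myelin markers turning direction without aged control 2. The same held for neocortical genes without aged control 2 or 3 or BDNF 1 or 3 (up to 0.335) and ribosomal proteins without aged control 2 or 4 or BDNF 4 (up to 0.332).

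In the hippocampus the 2 eGFP arrays were compared with 4 aged controls, and 5 named genes rose. Cd74 rose by 2.01 ± 0.29 (10.86 ± 0.50 in eGFP and 8.86 ± 0.34 in control arrays, n = 2 and 4, limma adjusted p = 0.0461) and RT1-Ba by 1.72 ± 0.23 at 1 of its 4 probe sets (adjusted p = 0.0334), with its brightest probe set at 0.13. Plac8, first described in placenta, rose by 1.24 ± 0.16 (adjusted p = 0.0325), Ubd, a ubiquitin-like protein induced by interferon, by 1.20 ± 0.17 (adjusted p = 0.0338), and Jchain, the joining chain of secreted antibodies, by 0.79 ± 0.11 (6.64 ± 0.04 and 5.85 ± 0.06, adjusted p = 0.0338; 0.32 at its second probe set). RT1-Bb (1.92), RT1-Da (1.91), Vangl2 (0.76), Cga (0.57) and Pcdha12 (0.54) did not pass (adjusted p from 0.0712 to 0.144), nor did Myo1d (-0.63), Mamdc2 (-0.63), Arhgap18 (-0.61), the myelin gene Mal (-0.58) and Rhbdd1 (-0.54). In all, 7 probe sets changed, all higher, 2 of them without a single symbol (4.39 and 2.51). No array could be left out with all 5 genes still past the threshold. Without eGFP 1 or aged control 2, 3 or 4 all 5 were lost (adjusted p from 0.0829 to 1). Without eGFP 2 all but Plac8 were lost, and without aged control 1 Cd74 (0.0562) and Jchain (0.0621). The count was 3 without eGFP 1, 1 without eGFP 2, 5 without aged control 1, and 0 without aged control 2, 3 or 4. It was also 0 with only both groups or all 27 arrays in the fit or with the brighter probe sets alone, and 3 with an intensity trend, which ended the calls of Cd74 (0.344), RT1-Ba and Jchain (0.0567 each).

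Myelin markers were lower in hippocampal eGFP than aged control arrays (median -0.372, list adjusted p = 5.73e-14, adjusted p = 0.634 with an estimated correlation), with 30 of 31 members below 0 and 5 falling when adjusted over the list alone, among them Mal and Myrf (-0.51 ± 0.14). MHC genes were higher by a median of 0.146 (list adjusted p = 1.16e-09, adjusted p = 0.549 with an estimated correlation), with Cd74 rising and 4 of 26 when adjusted over the list alone. Interferon response genes (0.107, list adjusted p = 8.87e-07; Cxcl9 0.81 ± 0.19, limma adjusted p = 0.0337 over the list alone, 0.44 without eGFP 1), microglia markers (0.13, 0.00028; Cd68 0.49 ± 0.16) and complement (0.121, 0.00896; C1qa 0.41 ± 0.12) had adjusted p = 0.697, 0.697 and 0.549 with an estimated correlation. T and B cell markers were higher by 0.077 (list adjusted p = 0.00196, adjusted p = 0.739 with an estimated correlation), with Jchain rising and 2 of 25 over the list alone. Astrocyte markers (-0.111, list adjusted p = 0.00345, Vim -0.47 ± 0.16), endothelial markers (-0.118, 0.00751, Flt1 -0.34 ± 0.12) and meningeal genes (-0.131, 0.0188, Slc13a4 -0.46 ± 0.16, or -0.29 without eGFP 1) were lower, with adjusted p = 0.728, 0.697 and 0.739 with an estimated correlation. Ribosomal proteins were higher (0.052, list adjusted p = 0.00274, adjusted p = 0.807 with an estimated correlation). Calls were lost for T and B cell markers without eGFP 1 or aged control 4 (up to 0.078), meningeal genes without eGFP 2 or aged control 1 (up to 0.435) and ribosomal proteins without eGFP 2 or aged control 3 (up to 0.909), which turned direction without eGFP 2. The other 7 calls stood without each of the 6 arrays.

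BDNF and aged control arrays of the hippocampus were compared last (2 and 4 arrays). Blood transcripts were highest in BDNF 2, with Hbb at 11.88 (10.18 in BDNF 1) and Alas2, a heme synthesis enzyme of red cells, at 7.38 (5.55 in BDNF 1). The group differences were 1.58 ± 0.32 for Hbb (11.03 ± 1.20 and 9.45) and 1.27 ± 0.34 for Alas2, or 0.73 and 0.35 without BDNF 2 and 2.43 and 2.19 without BDNF 1. In all 3 of 16 blood cell genes passed over the list alone and 0 over all probe sets in limma (median 0.016, list adjusted p = 0.0165, adjusted p = 0.739 with an estimated correlation). T and B cell markers were higher by a median of 0.171 (list adjusted p = 0.00113, adjusted p = 0.739 with an estimated correlation), with the cytotoxic gene Prf1 at 1.67 ± 0.54 and Ccl5 at 1.60 ± 0.51. These rested on BDNF 2, without which Prf1 stood at 0.10 and Ccl5 at 0.12. The list mean was 5.11 in BDNF 2 and 4.239 in BDNF 1. Myelin markers (-0.243, list adjusted p = 8.26e-06; Ermn -0.78 ± 0.24) and meningeal genes (-0.185, 25 of 31 below 0, 0.00839; Lum -1.0 ± 0.30 but Fn1 0.70 ± 0.26) were lower, with adjusted p = 0.739 each with an estimated correlation. Ermn stood at -0.22, Lum at -0.16 and Fn1 at 0.02 without BDNF 2, and at -1.34, -1.83 and 1.38 without BDNF 1. Ribosomal proteins (0.10, 35 of 41 above 0, list adjusted p = 2.01e-05, Rps3 0.21 ± 0.12 but Rpl28 -0.29 ± 0.17) and mitochondrial genes (0.041, 0.00839, Ndufb8 0.23 ± 0.12) were higher, with adjusted p = 0.739 and 0.808 with an estimated correlation. Without aged control 3 Rps3 stood at 0.11 and Ndufb8 at 0.15, and Rpl28 at -0.05 without BDNF 1 and -0.54 without BDNF 2.

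Single genes of that comparison with the smallest p-values were Bcl11b (1.07), Slc16a13 (0.69), Cp (0.64), Kif5a (0.62), Gimap7 (0.51), Clca1 (-0.97), Npas3 (-0.56), Agmo (-0.53), Mcoln2 (-0.47) and Megf11 (-0.41), with limma adjusted p from 0.459 to 0.618. With limma 0 probe sets changed, and 2380 were at an unadjusted p below 0.05 (1194 higher and 1186 lower) where chance gives 1552. Without BDNF 1, which leaves BDNF 2 alone in its group, 141 changed, among them Hbb (2.43), Prf1 (3.24) and Ccl5 (3.07). There was 1 without aged control 2 or BDNF 2. The ribosomal call stood without each of the 6 arrays (list adjusted p at most 0.0285). Myelin markers lost theirs without BDNF 2 (0.59) and mitochondrial genes without aged control 3 or BDNF 2 (up to 0.396). So did T and B cell markers (up to 0.358) and blood genes (up to 0.979) without aged control 4 or BDNF 2, with T and B cell markers turning direction without BDNF 2, and meningeal genes without aged control 1 or BDNF 2 (up to 0.274).

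**Figure D3:**
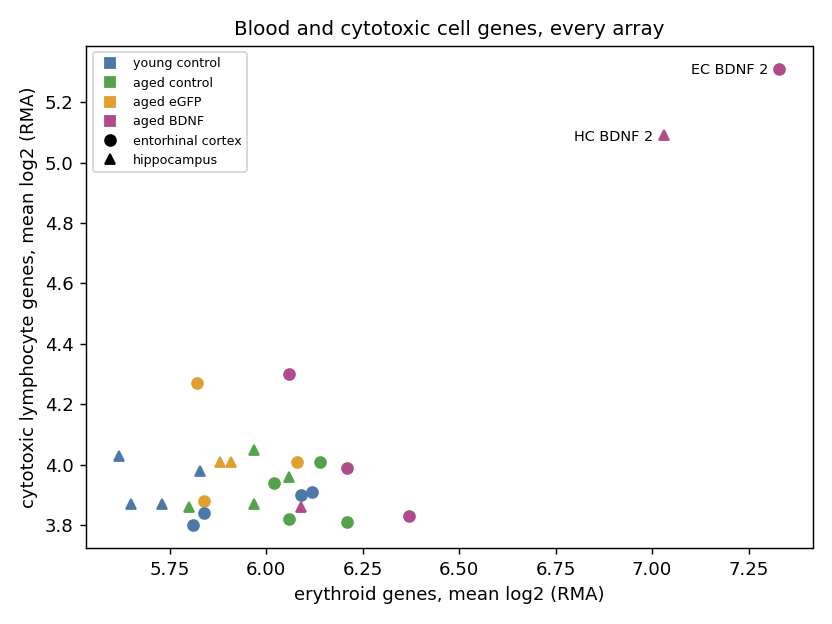
Mean log2 value of erythroid genes (x axis) and of cytotoxic lymphocyte genes (y axis) in each array, by region and group (1 point per array, no error bars). BDNF 2 of the entorhinal cortex (7.33 and 5.31) and BDNF 2 of the hippocampus (7.03 and 5.09) lay apart from the other arrays of their regions.

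Whether effects differed between the regions was tested with interactions over all 27 arrays, which treat the regions as independent although whether they share rats is unknown. For age, the microglia (median -0.318, list adjusted p = 8.56e-06, adjusted p = 0.723 with an estimated correlation) and MHC lists (-0.098, 0.008, adjusted p = 0.739 with an estimated correlation) had smaller effects in the entorhinal cortex than in the hippocampus, and the mitochondrial list a higher one (0.11, 1.16e-09, adjusted p = 0.697 with an estimated correlation). These 3 calls stood without each of the 16 control arrays. For BDNF minus eGFP, myelin markers had a lower effect in the entorhinal cortex (median -0.287, list adjusted p = 8.34e-05, adjusted p = 0.739 with an estimated correlation; 0.303 without hippocampal BDNF 1) and neuropeptides a higher one (0.223, 0.00829, adjusted p = 0.697 with an estimated correlation; 0.214 without hippocampal BDNF 1). In limma 0 probe sets passed in either interaction, with 1367 and 1888 at an unadjusted p below 0.05 where chance gives 1552. The genes of smallest p for age were Pcdhb17 (-0.82 ± 0.18), Bok (0.61 ± 0.14) and Galr2 (-0.87 ± 0.20).

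An ageing score asked whether BDNF arrays lay closer to young controls than eGFP arrays did. It was the mean of the 100 probe sets most raised minus the 100 most lowered with age among controls of the region, which chose them and serve only as reference. In the entorhinal cortex the score was 0.11 ± 0.17 in BDNF (n = 4; -0.022, 0.273, -0.035 and 0.24) and 0.30 ± 0.05 in eGFP arrays (n = 3), a difference of -0.18 (exact permutation p = 0.171, 2-sided; the smallest possible is 0.0286). Aged controls stood at 0.30 ± 0.04 and young controls at -0.50 ± 0.04. There 0 probe sets changed with age, so selection can make this gap. In the hippocampus the score was 1.81 ± 0.09 in BDNF and 1.86 ± 0.07 in eGFP arrays (n = 2 each), a difference of -0.05 (exact permutation p = 0.667, 2-sided; the smallest possible is 0.333). Aged controls stood at 2.13 ± 0.07 and young controls at 1.01 ± 0.11. This score holds Cd74 and RT1-Ba, which also rose with eGFP, so it does not track age alone. The difference was 0.01 without BDNF 2 and -0.20 without young control 1, and the entorhinal one -0.10 without young control 4.

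**Figure D4:**
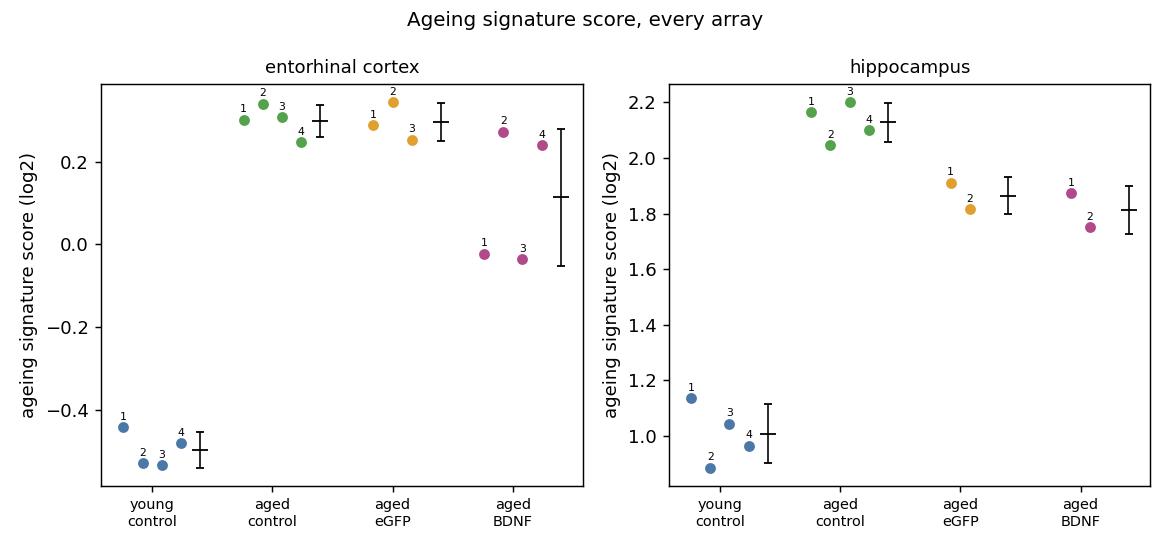
Ageing score (log2, y axis) of each array by group (x axis), in both regions (points are arrays, bars are mean ± SD). In the entorhinal cortex BDNF arrays stood at 0.11 ± 0.17 and eGFP arrays at 0.30 ± 0.05.

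Of the genes fixed in advance, 13 were measured in each comparison. Adjusted by limma over these genes alone, the rises with age in the hippocampus were Cd74, C3 (1.23 ± 0.25, adjusted p = 0.00159), Aif1 (0.43), Gfap, an astrocyte filament (0.37), and Ntrk2, which encodes TrkB (0.22). In BDNF against eGFP hippocampus, Cd74, C3 (-1.52 ± 0.35), the choroid plexus transcript Ttr (-0.99 ± 0.30) and Aif1 (-0.59 ± 0.21) were lower. Without BDNF 2, C3 stood at -0.78 and Aif1 at -0.15 (Aif1 at -1.03 without BDNF 1), and Ttr at -0.44 without eGFP 1 and -1.54 without eGFP 2. In eGFP against aged control hippocampus, Cd74, C3 (0.96 ± 0.30) and Ttr (0.83 ± 0.26) were higher, with Ttr at 0.28 without eGFP 1 and 1.37 without eGFP 2. In eGFP against aged control entorhinal cortex Cd74 was higher (limma adjusted p = 0.00257). Bdnf differed by -0.18 ± 0.20 between hippocampal BDNF and eGFP arrays (8.97 ± 0.30 and 9.15 ± 0.12, n = 2 each), by -0.22 ± 0.14 with age in the hippocampus (-0.35 without aged control 2, -0.11 without aged control 3) and by 0.07 in the entorhinal cortex. In entorhinal BDNF against eGFP arrays Vgf stood at 0.15, Ntrk2 at -0.10, Gfap at -0.08, Aif1 at -0.26, C3 at -0.58, Cd74 at -1.84 ± 0.99, Mbp at -0.17 and Ttr at 0.10, none past either threshold. Without eGFP 2 C3 stood at 0.05 and Aif1 at 0.10, the other direction, and without eGFP 3 at -1.68 and -0.82. They were -0.11 and -0.07 without eGFP 1, -0.09 and -0.01 without BDNF 2, and -1.01 and -0.48 without BDNF 4. Cd74 stood at -0.91 without BDNF 2, -1.10 without eGFP 2 and -3.12 without eGFP 3.

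The fixed genes not yet given were these, none past either threshold with all arrays. With age in the entorhinal cortex Ntrk2 stood at -0.01, Arc at -0.41 ± 0.49, Egr1 at -0.41 ± 0.22, Vgf at 0.15, Npy at -0.05, Sst at 0.15, Gfap at 0.34 ± 0.18, Aif1 at 0.05, Cd74 at -0.07, C3 at 0.63 ± 0.62, Mbp at 0.08 and Ttr at -0.22. Arc ran from -0.69 without aged control 2 (-0.66 without young control 3) to -0.12 without aged control 1. Ttr was -0.41 without young control 1, -0.34 without young control 2, -0.14 without aged control 1 and turned to 0.06 without young control 3. In entorhinal eGFP against aged control arrays C3 stood at 1.55 ± 0.67, or 0.92 without eGFP 2 and 2.64 without eGFP 3 (adjusted p = 0.0302), and Aif1 at 0.45 ± 0.36, or 0.26 without eGFP 1, 0.09 without eGFP 2 and 1.01 without eGFP 3. Arc was -0.53 ± 0.53 there, but -0.94 without eGFP 2, -0.81 without aged control 1, -0.25 without aged control 2 and -0.12 without eGFP 3. Ttr was -0.28 (-0.18 without aged control 3 or eGFP 2) and Sst -0.21 (-0.13 without aged control 1). Bdnf (-0.11), Ntrk2 (0.03), Egr1 (-0.01), Vgf (-0.15), Npy (-0.12), Gfap (0.12) and Mbp (0.09) complete that comparison. In entorhinal BDNF against aged control arrays Cd74 stood at 2.94 ± 0.91 (adjusted p = 0.0727 over these genes alone), C3 at 0.96 ± 0.62 (1.46 without BDNF 2, 0.53 without BDNF 4) and Npy at 0.33 ± 0.17 (0.16 without aged control 2). Egr1 was 0.23, or 0.35 without aged control 2, 0.49 without BDNF 2, 0.09 without aged control 1 and 0.05 without BDNF 3. Arc (0.19), Aif1 (0.19), Gfap (0.04), Sst (0.01), Vgf (0.00), Bdnf (-0.02), Ntrk2 (-0.07), Mbp (-0.08) and Ttr (-0.18) were the others.

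Hippocampal values of the fixed genes with age were -0.41 ± 0.21 for Ttr, -0.28 for Egr1, -0.18 for Vgf, -0.16 for Arc, -0.04 for Npy, -0.01 for Sst and 0.12 for Mbp. For BDNF against eGFP they were 0.14 for Arc, 0.11 for Vgf, 0.09 for Mbp, -0.04 for Sst, -0.05 for Ntrk2, -0.06 for Npy, -0.13 for Egr1 and -0.16 for Gfap. In eGFP against aged control hippocampus Bdnf stood at 0.23 ± 0.17 (0.36 without aged control 2, 0.14 without eGFP 1 and 0.12 without aged control 3) and Arc at -0.45 ± 0.34 (-0.85 without eGFP 2, -0.29 without aged control 2 and -0.05 without eGFP 1). Aif1 was 0.23, Egr1 and Gfap -0.01, Npy -0.10, Ntrk2 -0.14, Sst -0.16, Mbp -0.19 and Vgf -0.20. In BDNF against aged control hippocampus C3 stood at -0.57 ± 0.30, Aif1 at -0.36 ± 0.18, Arc at -0.31 ± 0.34 and Sst at -0.20. Without BDNF 2 these were 0.18, 0.07, 0.32 and -0.47. Without BDNF 1, which leaves BDNF 2 alone in its group, they were -1.32, -0.80, -0.93 and 0.07. Arc was also -0.47 without aged control 1 and -0.15 without aged control 2. Ntrk2 (-0.19), Gfap (-0.17), Ttr (-0.17), Npy (-0.16), Egr1 (-0.14), Mbp (-0.10), Vgf (-0.09), Cd74 (-0.03) and Bdnf (0.04) complete the set.

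Lists with no call in any comparison were TrkB and neurotrophin signalling (smallest list adjusted p = 0.101), presynaptic vesicle machinery (0.0579), glutamate receptors and postsynaptic density (0.0661), protein folding and heat shock (0.155), oligodendrocyte progenitor and cell cycle genes (0.0765), hippocampal neuron genes (0.301) and striatal and thalamic genes (0.155). Over the 280 list tests 91 passed with the preset correlation, 50 higher and 41 lower, and 0 with an estimated correlation (smallest adjusted p = 0.144; 19 at an unadjusted p below 0.05). By fry, which tests whether the genes of a list move on balance in the same direction, 2 passed: complement and microglia with age in the hippocampus (adjusted p = 0.0115 each). Across all lists and within-region comparisons, limma over all probe sets gave 10 rises of list members and 0 falls. Cd74 is counted both with age and with eGFP in the hippocampus.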

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

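Tests of the 3 patterns weighed in this part were all chosen only after the results were seen, and the bounds of those on a vector response and on blood of the same makeup were set again after their values were known; the region interactions were planned.

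In the entorhinal cortex the mean of the microglia, MHC, interferon and complement lists was higher in eGFP than in aged control arrays by 0.63 (exact p = 0.0286, 2-sided, the smallest possible), with arrays at 7.32, 7.55 and 6.74 against 6.48 to 6.65. The lists were pooled after they had been called higher in these same arrays, so this p repeats the selection. Blood left in the tissue was argued against by erythroid genes, at -0.20 in eGFP minus aged control arrays (exact p = 0.143). More meningeal or choroid plexus tissue in the dissection was argued against by the mean of those lists, at -0.06 (exact p = 0.257). A response to the vector or its infusion, with which the BDNF arrays would also be higher, may explain the pattern and stays open: BDNF minus aged control arrays gave 0.38 with an exact p of 0.0571, and whether controls were infused is unknown. With arrays at 6.78, 6.62, 6.94 and 7.48, BDNF minus eGFP was -0.25 (exact p = 0.429).

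BDNF 2 stood apart in both regions through cytotoxic lymphocyte genes, with a mean of 5.31 in the entorhinal cortex (the other arrays 3.80 to 4.30) and 5.09 in the hippocampus (3.86 to 4.05); 12 of the 17 genes lay above all other arrays in both regions. Entry of cells at the entorhinal infusion site alone was argued against by nearly equal excesses, 1.36 and 1.15, which differ by 0.21. The BDNF vector as the source in all its arrays was argued against by entorhinal BDNF 1, 3 and 4, at -0.01 from the 3 eGFP arrays (-0.08 as the mean with the hippocampus, where -0.15 rests on BDNF 1 alone), but entorhinal BDNF 4 was the highest other array of its region for Prf1 (4.61), Nkg7 (4.94), Ccl5 (7.53, median 5.30), Eomes (3.70), Cd8a (4.25) and Cd8b (4.97), so an effect in some of them stays open. More blood of the same makeup cannot be told apart from other sources: erythroid genes had excesses of 1.28 and 1.17, and 3 of 17 cytotoxic genes (Prf1, Gzmk and Ccl5) exceeded Hbb in both regions (Hbb 2.22 and 2.58, Prf1 3.43 and 3.21). Against such blood run Cd3d, Cd3e, Cd3g and Ms4a1, below the medians of the other arrays in both regions (2.90, 4.59, 3.15 and 3.86 against 3.13, 4.85, 3.43 and 4.05 in the entorhinal cortex). Cd3e had a far higher median in the hippocampus (8.05, with BDNF 2 at 7.75). Ptprc, of the microglia list, cannot tell blood from other immune cells. It was 6.23 in entorhinal (other median 5.16, highest 6.75) and 5.89 in hippocampal BDNF 2 (5.17, 5.73). Red cell genes were mixed, with Ahsp (4.91 and 4.32) above all other arrays in both regions, Slc4a1 above the medians (5.41 against 5.29 and 5.42 against 5.18) and Epb42 near them (3.50 against 3.54 and 3.50 against 3.49). Most of these values are low and exclude nothing, and other biological explanations were not tested.

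MHC class II genes were higher in aged than in young hippocampal controls by 1.13 (exact p = 0.0286, 2-sided, the smallest possible). Their list was written after their rise in these same arrays had been seen, so this p repeats the selection. A higher share of unaltered microglia would raise the microglia list by as much. That list without class II genes stood at 0.36 (exact p = 0.0286), a gap of 0.77 (exact p = 0.0286). The selection of class II genes favoured such a gap, so the test does not decide. The RNA quality of aged control 3 (actin difference 3.52) was argued against by 4 of 6 class II probe sets that stayed past the threshold without that array. A change of expression with age within microglia, or entry of other cells that carry class II, may explain the 0.77 and was not tested.

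Single arrays far from the other 3 of their group were marked by Dixon's test, which marks about 1 in 20 groups by chance; here it marked 18 of 271 (6.64%). Neuronal list means were high for presynaptic genes in entorhinal BDNF 2 (9.32, the others up to 9.28) and hippocampal young control 4 (9.29, up to 9.15), and for pan-neuronal markers in entorhinal aged control 2 (11.19, up to 11.08). Metabolic list means were high for cholesterol synthesis in hippocampal aged control 4 (8.81, up to 8.69) and for mitochondrial genes in entorhinal aged control 1 (11.17, up to 11.08). Complement was low in hippocampal aged control 2 (7.05, the others from 7.14), and microglia markers were high in entorhinal BDNF 4 (7.69, up to 7.17). Myelin markers were high in entorhinal aged control 2 (9.44, up to 8.84) and endothelial markers in entorhinal young control 2 (7.57, up to 7.25). Blood cell genes were high in entorhinal BDNF 2 (6.17, up to 5.43) and hippocampal young control 1 (5.19, up to 5.07). Low single genes were Arc in entorhinal young control 3 (8.75, from 9.70), Sst in hippocampal aged control 2 (10.34, from 10.39), RT1-Da and Cdh23 in hippocampal young control 2 (5.36, from 6.03, and 5.18, from 5.33) and Gpr143 in hippocampal young control 1 (3.50, from 3.80). Ptpro was high in hippocampal aged control 1 (6.81, up to 6.66), and the actin difference in hippocampal aged control 3 (3.52, up to 2.84).

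For the effect of age 10 lists were called in the planned interaction of the regions (list adjusted p from 1.16e-09 to 0.0465 with the preset correlation, from 0.697 to 0.801 with an estimated correlation). Chance is not excluded for such a count. Adjusted within the comparison 11 lists were called, and 9 of 100 splits of the arrays, the real one included, gave as many. Mean log2 effects, entorhinal minus hippocampal with both regions in brackets, were 0.112 for GABAergic genes (0.046, -0.066), 0.116 for pan-neuronal markers (0.064, -0.052) and 0.116 for mitochondrial genes (0.02, -0.097). Immune lists had -0.168 for complement (0.137, 0.305), -0.392 for MHC genes (0.058, 0.449) and -0.279 for microglia markers (0.08, 0.359). Glial and vascular lists had -0.091 for astrocyte (0.03, 0.121), -0.133 for myelin (0.093, 0.226), -0.144 for endothelial (-0.087, 0.056) and -0.125 for meningeal genes (-0.095, 0.03). Mitochondrial, MHC and microglia calls stood without each array. Without entorhinal young control 2 endothelial (0.152), pan-neuronal, complement, astrocyte and meningeal calls were lost, the last 4 also without others, with list adjusted p of up to 0.262 (entorhinal aged control 2, hippocampal young control 4 and aged control 1), 0.213 (entorhinal aged control 2, hippocampal young control 2 and 3 and aged control 1), 0.715 (entorhinal aged control 1, hippocampal young control 2) and 0.411 (entorhinal young control 4 and aged control 4, hippocampal young control 2 and aged control 1). GABAergic genes were lost without entorhinal young control 2 or 4, aged control 1 or 4, or hippocampal young control 1, 3 or 4 or aged control 1 or 3 (up to 0.198). Myelin was lost without entorhinal young control 3, aged control 1, 3 or 4, or hippocampal young control 2 or aged control 2 (up to 0.218).

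For the effect of BDNF against eGFP 8 lists were called in the interaction of the regions (list adjusted p from 8.34e-05 to 0.0357 with the preset correlation, from 0.549 to 0.807 with an estimated correlation). Neuronal lists had 0.157 for immediate early genes (0.191, 0.034), 0.17 for neuropeptides (0.146, -0.024) and 0.113 for channels (0.108, -0.005). Glial, vascular and other lists had -0.23 for astrocyte (-0.124, 0.106), -0.306 for myelin (-0.23, 0.076), -0.249 for endothelial (-0.118, 0.131), 0.133 for choroid plexus (0.037, -0.096) and -0.094 for ribosomal genes (-0.061, 0.033). Without hippocampal BDNF 1 the calls of neuropeptides (0.214), channels (0.0721, also without eGFP 1), myelin (0.303) and endothelial genes (up to 0.218, also without entorhinal BDNF 1 or eGFP 2) were lost. Without entorhinal eGFP 2 those of astrocyte (0.0863) and ribosomal genes (up to 0.741, also without hippocampal eGFP 1) were lost. Immediate early genes were lost without entorhinal eGFP 3, BDNF 1 or 3 or hippocampal eGFP 2 or BDNF 2 (up to 0.364), and choroid plexus genes without entorhinal eGFP 1 or 2 or BDNF 2 or hippocampal eGFP 1 or BDNF 2 (up to 0.294).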

How the results depend on the processing

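List tests under other scalings, a block or left-out arrays, and the joint omission of entorhinal eGFP 3 and BDNF 2 of both regions, were chosen only after the results were seen; the cause of the changes in this part was not tested unless fewer arrays or probe sets show it.

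The 32 probe sets called with age in the hippocampus became 58 with an intensity trend and 55 with array weights (31 of the 32 in each), 23 with all 27 arrays (14 of the 32), 24 with the brighter probe sets (19), 27 with the replicate block (25), 29 with only both groups (25), 35 with quantile normalization (31), 33 with median centring (31), 39 with 1 probe set per gene (24), 51 at an adjusted p below 0.10, and 7 (without young control 3) to 30 (without aged control 2) with an array left out. The 7 of hippocampal eGFP minus aged control became 0 with only both groups, all 27 arrays or the brighter probe sets, 3 with a trend, 5 with the replicate block (3 of the 7), 11 with array weights or at 0.10, and 0 (without aged control 2) to 5 (without aged control 1). The 0 of entorhinal eGFP minus aged control became 2 with only both groups, 38 with all 27 arrays, 3 with the brighter probe sets, quantile normalization or a trend, 70 with weights, 8 with 1 probe set per gene, 16 at 0.10, 233 with the joint omission, and 0 to 169 (without eGFP 3). The 0 of entorhinal age became 1 with only both groups, and those of BDNF minus aged control 8 (entorhinal) and 1 (hippocampus) with the joint omission. The latter ran from 0 to 141 (without BDNF 1). The 0 of hippocampal BDNF minus eGFP became 4 with the replicate block, 3 with weights or at 0.10, 2 with 1 probe set per gene, 1 with the joint omission, and 0 to 81 (without BDNF 1). Both interactions stayed at 0 by limma with each array left out. An array alone in its group was assumed to vary like the other groups.

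The ageing score difference reversed to 0.09 in the entorhinal cortex with the 1 probe set past the threshold (exact p = 0.743), and in the hippocampus to 0.01 with the larger number of probe sets in each direction, to 0.04 with the other region's probe sets and to 0.01 without BDNF 2. It otherwise ran from -0.23 to -0.10 and, in the hippocampus, from -0.20 (without young control 1). The 91 list calls became 0 with an estimated correlation, 2 by fry, and 82 to 99 with an array left out.

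Of the 21 named genes that passed, 21 did so with quantile normalization, 16 with the replicate block and 6 with all 27 arrays. The block ended the calls of Slc35d3 (adjusted p = 0.0771), Lgals3 (0.079) and Cd53 (0.0853) with age in the hippocampus and of Ubd (0.384) and Jchain (0.178) in hippocampal eGFP minus aged control; over 158 omissions 75 passed, and 0 reversed. The labels do not say that replicate numbers pair the regions. Of 12 pairs with the same group and number, 8 had deviations correlated above 0.1 and 1 below -0.1 (from -0.114 to 0.424), and 4 were best matches. Same numbers in different groups gave 4 of 21 above 0.1 and 4 below -0.1 in the entorhinal cortex, and 3 of 14 above and 6 below in the hippocampus. Those 3 were all young against aged controls (0.306, 0.244 and 0.196), whose remaining pair, number 3, had 0.042. Pairing of some arrays is therefore left open, and the regions were treated as independent. Signal over background was not tested apart from the brighter probe sets. Group sizes limit small changes. At a log2 change of 0.5, 16% (hippocampal BDNF minus eGFP) to 72% (entorhinal eGFP minus aged control) were recovered. This change was simulated in brighter probe sets alone and beside larger changes, which ease the adjusted threshold.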

Other observations

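Splits of the samples were run for 6 comparisons and planned for 5 of them, those of age in the entorhinal cortex being chosen only after the result was seen, and the test of hippocampal genes in the entorhinal cortex was chosen only after some of their values were seen.

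The 32 probe sets that changed with age in the hippocampus were read in the entorhinal cortex, where 27 had the same sign. Their signed mean differed by 0.34 between aged and young controls (exact p = 0.0286, 2-sided, the smallest possible), with aged arrays at 4.77, 4.77, 4.77 and 4.75 and young arrays from 4.37 to 4.48. Cdh1 stood at 1.05, Cyp2a3 at 0.93, Cdh23 at 0.89, Ecrg4 at 0.81 and Serping1 at 0.67, but Cd74 at -0.07, RT1-Bb at -0.06, RT1-Ba at 0.14 and RT1-Da at 0.23. The median was 0.29, against 0.82 in the hippocampus, where the probe sets were chosen. A change with age shared by both regions may explain the 0.34, but the regions may come from the same rats, and a batch shared by the age groups was not tested.

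The mean of a list of stress-response genes, written after the data were seen, was highest in 3 arrays: entorhinal eGFP 3 (9.28), entorhinal BDNF 2 (8.72) and hippocampal BDNF 2 (8.97), with the other 24 arrays at 7.25 to 7.97. Angpt2 was 9.26, 7.25 and 7.62 in them (3.77 to 5.17 in the others), Adm 6.98, 5.66 and 5.77 (3.55 to 4.51), Pdk4 8.63, 8.57 and 8.89 (6.20 to 8.24) and Cdkn1a 8.84, 8.43 and 8.88 (7.08 to 7.98). The rest of the 9 genes did not set all 3 arrays apart: Fkbp5 was 9.50 in entorhinal eGFP 3 (the others up to 9.56), Sgk1 11.01 in entorhinal BDNF 2 (up to 11.28), Tsc22d3 10.56 in hippocampal BDNF 2 (up to 10.56), Vegfa 8.40 and 8.25 in both BDNF 2 arrays (up to 8.68) and Per1 8.51 to 8.68 in the 3 (up to 8.79).

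Chance as the grouping of the arrays was examined by splitting them in other ways. For age in the hippocampus 1 of 35 splits, the real one, gave as many as 32 probe sets past the adjusted threshold and the highest other gave 0. This makes chance less likely for that count but does not exclude it. No share below 1 of 35 was possible, and 6 comparisons were split with no allowance for their number. Chance is also left open for the 2362 probe sets of the same comparison at an unadjusted p below 0.05 (7 of 35 splits as large, highest other 2765, with replicates 1 and 2 of both ages against 3 and 4), and for the counts that follow. No splits were run for the hippocampal comparisons that involve a vector, the 7 probe sets of eGFP minus aged control included, or for the BDNF interaction. For probe sets at an unadjusted p below 0.05, entorhinal age had 847 (24 of 35 splits as large, highest other 2704), BDNF minus eGFP 1487 (25 of 35, 4989), eGFP minus aged control 3006 (5 of 35, 3855), BDNF minus aged control 1117 (15 of 35, 2442) and the age interaction 1367 (56 of 100, 2620). The 2704 and 4989, several times the real counts, came from 1 split each. The first set young control 2 and 4 and aged control 2 and 3 against the other 4 controls, and the second set BDNF 1 and eGFP 1 and 2 against BDNF 2, 3 and 4 and eGFP 3. Each was picked as the highest of the other splits. Whether they reflect a structure of the samples other than the groups compared was not tested. For lists adjusted within the comparison, the counts were 4 for entorhinal age (27 of 35, highest other 13), 18 for BDNF minus eGFP (2 of 35, 18), 11 for eGFP minus aged control (6 of 35, 17), 11 for BDNF minus aged control (6 of 35, 11), 8 for hippocampal age (14 of 35, 18) and 11 for the age interaction (9 of 100, 17).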
